A study of Mus musculus with 6 samples.

How the data were processed

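The samples were 6 two-colour Agilent arrays of 60-mer probes, each hybridised for 17 hours with 750 ng of Cy3-labelled and 750 ng of Cy5-labelled cRNA. The RNA came from pools of 10 uteri of 19 day old mice, from litters of 8 female pups, that had been given diethylstilbestrol in corn oil or corn oil alone on days 1 to 5. Per the labels the scanner images were read with Feature Extraction 7.4. Per the file headers the mean signal and the median local background of a spot are intensities on a linear scale that the authors did not normalise. The deposited processed signals are intensities after background subtraction with spatial detrending and dye normalisation. The deposited log ratio of each array is log10 of Cy5 over Cy3, and the deposited p-value (p_value) of a spot, per the file headers, comes from the software's error model. The authors' series matrix holds log2 of DES over control, found by setting each of its columns against the array's log ratio (slopes of -3.32 and 3.32 for the 2 dye orders, correlations of at least 0.9997 in size). All 6 arrays were extracted on the same day and no slide held more than 1 dose, so no batch could be set against the dose and a batch block could not be run.

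Groups were taken from the titles of the samples. Replicate 1 of a dose carried DES in Cy3 and replicate 2 in Cy5. Both arrays compare the same pair of pools, so they were averaged and counted as 1 value, and p values rest on the spread between pools. The median signal of an array was between 168.9 and 327.7 over a background of 53 to 60, which leaves dim probes close to the background. Log ratios near the floor are pulled to 0 by the offset.

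From the mean signals, ratios were made with limma 3.58.1 in R 4.3.3 by normexp background correction with an offset of 50 and loess within each array, with control and outlier spots at weight 0. Signs were turned so that DES is the numerator, spots of a probe were averaged, and the 2 arrays of a dose were averaged. Levels per pool were taken after quantile normalisation of the average intensities. A probe was tested when it was well above background in at least 1 dye on both arrays of at least 1 dose, which held for 19755 of 20868 probes, and 101 of these were left out because outlier spots left no value on an array, so that 19654 were tested. Symbols came from a table of RefSeq accessions (8947 probes), from symbols in the file's descriptions (358 current and 286 updated) and, for 54 members of the gene lists, from names spelled out in the descriptions. The last step was done after some values had been seen, for every unmatched list member alike. No symbol was found for 11223 probes. Where a gene had several probes, the brightest stood for it. Nos3 was the only named gene with more than 1 tested probe, and its 2 probes differed by 0.295, 0.282 and 0.0528 on the log2 scale at the 3 rising doses.

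The following were fixed before the data were examined. At each dose the ratio was divided by the square root of 2 times limma's moderated SD between the 3 control pools (squeezeVar, 9.06 moderated degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A DES pool is thus assumed to vary like the control pools. Differences between doses were tested in the same way with 4 pools. The 2-fold rule asks for a mean log2 ratio of at least 1 in size with at least 1.5-fold in 1 direction on both arrays and has no test. Change over the 3 doses was tested with limma (lmFit and eBayes) as the mean of the 3 ratios, and the trend as the slope on log10 dose with 1 residual degree of freedom. The ratio is paired by design, since each dose has its own control on the same array, but the spread in the test at a dose comes from control pools on different arrays and is not paired. Levels of a DES pool and its own control correlated at 0.9976, 0.9963 and 0.9935 across probes at the 3 rising doses, and those of control pools with each other at 0.9737 to 0.9921, so that this spread is wide for a paired ratio and the test strict.

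The 28 gene lists were 13 of pathways and 15 of cell types, fixed before the data were examined. They were tested over the 3 doses with camera (preset correlation 0.01, then estimated) and fry, with Benjamini-Hochberg adjustment over the 28 lists. At each dose the median of a list was ranked among 10000 random lists of the same size drawn from 20 bins of expression. Named genes were those past the threshold at each dose, filled up by the 2-fold rule to at most 10 in each direction, the 12 highest and 12 lowest over the 3 doses with 1 direction on all 6 arrays, by smallest p, up to 4 members per list with the largest change, and 13 genes set in advance, of which 12 were measured. Members of lists past the threshold adjusted over the list alone, genes past the technical test only, genes of the trend and of the differences, and members of the list of further brown fat genes were named after their values were seen, while that list itself was fixed before.

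A technical test was added after the values had been seen. It is a limma fit of the 6 arrays with a coefficient per dose and a dye term on 2 residual degrees of freedom. It compares the RNA pools on the arrays, not the conditions, since it leaves out the spread between pools. In it the dye effect itself passed at 1709 probes. The dye bias of a probe cancels in the mean of the 2 arrays.

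Camera and 5 tests of probes were checked on simulated data, while fry and the 6-array fit with a random block were not. The simulated data had 50 probes changed by each of 1.5-, 2-, 4- and 8-fold. The test at 1 dose recovered 2%, 68%, 100% and 100% of them, with 12.3% false calls. The test over the 3 doses recovered 82%, 100%, 100% and 100% with 14.7% false calls, the trend 4%, 30%, 100% and 100% with 21.5%, and the difference between doses 0%, 18%, 98% and 100% with 2.7%. The technical test recovered 100% at each size with 9.09% false calls. Camera recovered a list shifted by 0.2 and called 0 of the unshifted lists. The simulated genes were independent of each other, while the estimated correlation in the data was 0.389 for smooth muscle and 0.434 for cell cycle genes. The check therefore could not show false calls that come from correlated genes. The share of false calls was above the nominal 5% in 4 of the 5 tests. Apart from the technical test, pools were simulated as independent of each other with the spread of the control pools. The real ratios are paired, with an SD over probes of 0.0943, 0.117 and 0.155 at the rising doses against a median SE of 0.211. The simulated shares therefore need not hold for them.

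The alternatives tried were Feature Extraction's processed signals, an offset of 10, no background subtraction, median centring, scale normalisation between arrays, the series matrix values, no filter and a stricter one, each array left out, each control pool left out of the spread, the residual SD of the ratios as the spread, an intensity trend in the variances, all controls as 1 group, the software's own p under 0.01 on both arrays, a random block for the dose, each pair of pools left out, other settings of camera, and lists with the muscle and fat genes removed. Results for 4 genes are not reported here. Data were handled with the package data.table, version 1.17.8, and block correlations used statmod 1.5.0. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.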

Results

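Gene expression was measured in the uterus of 19 day old CD-1 mice, an outbred strain, that had been given diethylstilbestrol (DES), a synthetic estrogen, or corn oil alone on postnatal days 1 to 5. The doses were 1, 10 and 1000 µg/kg/day. Each dose had 1 DES pool and 1 corn oil control pool of its own, each made of RNA from 10 mice, and each pair of pools was hybridised on 2 two-colour arrays with the dyes exchanged. The 6 arrays held 20868 probes that were not controls, of which 19654 were tested. The median Cy3 signal was between 174.4 and 204.4 per array and the median Cy5 signal between 168.9 and 327.7, over a local background of 53 to 60. Between 92.3% and 95.3% of probes were well above background in at least 1 dye. The 2 arrays of a pair are technical repeats of 1 comparison of pools, so each dose has 1 biological value and no replicate of its own. The SE given with a ratio comes from the spread between the 3 control pools. The number of pools limits the precision. The levels of the control pools differed, with a median SD of 0.133 on the log2 scale. Each control pool was measured on its own arrays, so pool and array cannot be told apart in these levels. The controls of DES 10 and DES 1000 were at least 2-fold apart at 87 probes, those of DES 10 and DES 1 at 68, and those of DES 1000 and DES 1 at 4. The series title gives the question as whether exposure during development alters uterine expression in ways that bear on later neoplasia.

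The comparison at 1 µg/kg/day asked what the lowest dose left in the uterus on day 19, after dosing had ended on day 5. The highest ratios were those of 5 genes known from epithelia. Serpinb11, an epithelial serpin, was higher in the DES pool by 2.03 ± 0.42 on the log2 scale (SE from the 3 control pools), and Krt15, a keratin of basal epithelial cells, by 1.74 ± 0.76. Clca1, a secreted goblet cell protein, was higher by 1.44 ± 0.51, Il33, an epithelial alarm cytokine, by 1.20 ± 0.28, and Aqp5, a water channel of glands, by 1.09 ± 0.30. The 4 lowest genes included both calbindins, the calcium-binding proteins S100g at -1.23 ± 0.26 and Calb1 at -1.22 ± 0.25. Fxyd4, a regulator of the sodium pump, stood at -1.15 ± 0.25 and Hdc, which makes histamine, at -1.06 ± 0.27. These 9 genes are all the probes that met the 2-fold rule at this dose, 5 higher and 4 lower. None passed the test against the spread between control pools. That test (limma's moderated variance) called 0 probes at an adjusted p under 0.05, with 47 at an unadjusted p under 0.05, where chance alone would give 982.7. Its spread is that between control pools on different arrays. The residual SD of the 3 ratios in its place, a paired spread, also gave 0 calls. That SD takes in any change particular to 1 dose, so it could hardly call such a change. Median centring gave 1 call, Serpinb11 (adjusted p = 0.0483), and leaving the DES 1, DES 10 or DES 1000 control pool out of the spread gave 3, 1 and 1. A technical test on the arrays (limma), chosen after the values had been seen and comparing the 2 RNA pools rather than the conditions, called 25 probes, 14 higher and 11 lower, among them these 9. It called 1 probe with Feature Extraction's processed signals or the series matrix values and 3 with median centring. With processed signals the 2-fold rule was met by 29 probes, 12 higher and 17 lower. Without DES 1 replicate 1 it was met by 27, 12 higher and 15 lower, but with 1 array left the rule asks only for 2-fold on that array. Ltf, which encodes the iron-binding secretory protein lactotransferrin and is a classical estrogen response gene, stood at 0.99 ± 0.38.

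At 10 µg/kg/day, 4 probes rose and 0 fell. All 4 belong to genes known from brown adipose tissue and oxidative muscle. Cidea, a lipid droplet protein, rose by 3.69 ± 0.27 on the log2 scale (adjusted p = 0.00254), and Ucp1, the uncoupling protein of brown fat, by 2.83 ± 0.21 (adjusted p = 0.00254). Cox8b and Cox7a1, subunits of cytochrome oxidase found in muscle and brown fat, rose by 2.07 ± 0.20 and 2.02 ± 0.19 (adjusted p = 0.0112 for both). Each was higher on both arrays. The level of Cidea was 10.7 in the DES 10 pool and 6.67 and 6.68 in the other DES pools, and that of Ucp1 was 8.92 against 6.13 and 6.11, where it was well above background on 1 of 2 arrays. Markers of fat cells were higher in the same pool, with Fabp4 at 0.75, Cfd at 0.71 and Adipoq at 0.64. For Cfd the control pool of this dose was the low one, at 12.25 against 12.81 and 12.62 in the other control pools. The epithelial genes of the lowest dose had the same direction here, with Serpinb11 at 1.39 ± 0.42, Krt15 at 1.34 ± 0.76 and Il33 at 1.04 ± 0.28. Krt15 had a level of 9.41 in the DES 10 control pool and of 7.74 and 7.31 in the other control pools. Spink12, a protease inhibitor, stood at 1.15 ± 0.21. On the low side, Spp1, which encodes osteopontin, stood at -1.56 ± 0.55, the neutrophil protein S100a9 at -1.27 ± 0.34 and the keratin Krt23 at -1.08 ± 0.21. The cytotoxic granule genes Gzma and Gzmc stood at -0.90 and -0.74. For Spp1, Gzma and Gzmc the control pool of this dose was the high one, at 8.96, 7.42 and 7.43 against at most 7.72, 6.99 and 6.73 in the other control pools, while the highest of the DES pools lay at 7.80, 6.72 and 6.74. Of the probes, 14 met the 2-fold rule, 8 higher and 6 lower, and 11 of these carry a gene symbol. With processed signals or the series matrix values the rule was met by 39, 19 higher and 20 lower. Without DES 10 replicate 2, where it asks only for 2-fold on the lone array, it was met by 25. The test gave 83 probes at an unadjusted p under 0.05, and the technical test called 52, 26 in each direction, and 7 with processed signals, the series matrix values or median centring. All 4 calls ended with Feature Extraction's processed signals, with the series matrix values, with a normexp offset of 10 and without DES 10 replicate 1. They also ended with the residual SD of the 3 ratios as the spread, but that SD takes in the change at DES 10 itself. The ratios themselves stayed large, at 4.24 for Cidea, 4.35 for Ucp1, 2.38 for Cox8b and 2.34 for Cox7a1 with processed signals, and at 3.62, 2.72, 1.92 and 1.63 without DES 10 replicate 1. Without DES 10 replicate 2, or without DES 1000 replicate 2, 2 calls were left.

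At 1000 µg/kg/day, the highest dose, the lowest ratios among probes with a symbol were those of 2 troponins. Clca1 was higher by 2.11 ± 0.51, Ccn2, a matricellular growth factor, by 1.42 ± 0.28, Sfrp4, a secreted WNT antagonist, by 1.15 ± 0.22, Matn2, a matrix protein, by 1.03 ± 0.21 and Ltf by 1.02 ± 0.38. The troponins Tnni2 and Tnnt2, of the muscle thin filament, stood at -1.83 ± 0.25 and -1.80 ± 0.21. Tppp3, a tubulin-binding protein, stood at -1.45 ± 0.29, S100g at -1.26 ± 0.26, Krt23 at -1.21 ± 0.21, the fat cell protease Cfd at -1.16 ± 0.27 and Chrdl2, a BMP antagonist, at -1.08 ± 0.26. The test against the control pools called 0 probes (limma's moderated variance), with a smallest adjusted p of 0.234, for Tnnt2, and 223 probes at an unadjusted p under 0.05. The 2-fold rule was met by 23 probes, 13 higher and 10 lower, of which 13 carry a symbol. With processed signals it was met by 82, 54 higher and 28 lower, with the series matrix values by 79 and with an offset of 10 by 45. Without DES 1000 replicate 1, where it asks only for 2-fold on the lone array, it was met by 44, 20 higher and 24 lower. The technical test called 183 probes, 120 higher and 63 lower. With processed signals or the series matrix values it called 7, 1 higher and 6 lower, with median centring 16, 7 higher and 9 lower, and with scaling between arrays 0, so neither the count nor the excess of higher ones held. The arrays of this dose were unlike in spread. The log2 ratios of DES 1000 replicate 2 had an SD over probes of 0.274. It was 0.159 on replicate 1 and 0.154 to 0.209 on the arrays of the other doses. How far this raised the counts at DES 1000 was not tested. Among the 183 were Lox at 0.93, Snai2 at 0.92, Sfrp1 at 0.87, Dkk3 at 0.85, Mmp2 at 0.69 and Lum at 0.67. Foxa2, a transcription factor of uterine glands, stood at -0.66 and the cyclin Ccnd1 at -0.79, and the contractile genes Des and Cnn1 stood at -0.82 and -0.80. Median centring in place of loess gave 5 calls at this dose, among them Clca1, Ccn2, Tnni2 and Tnnt2, and leaving the DES 1 control pool out of the spread gave 8.

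**Figure D1:**
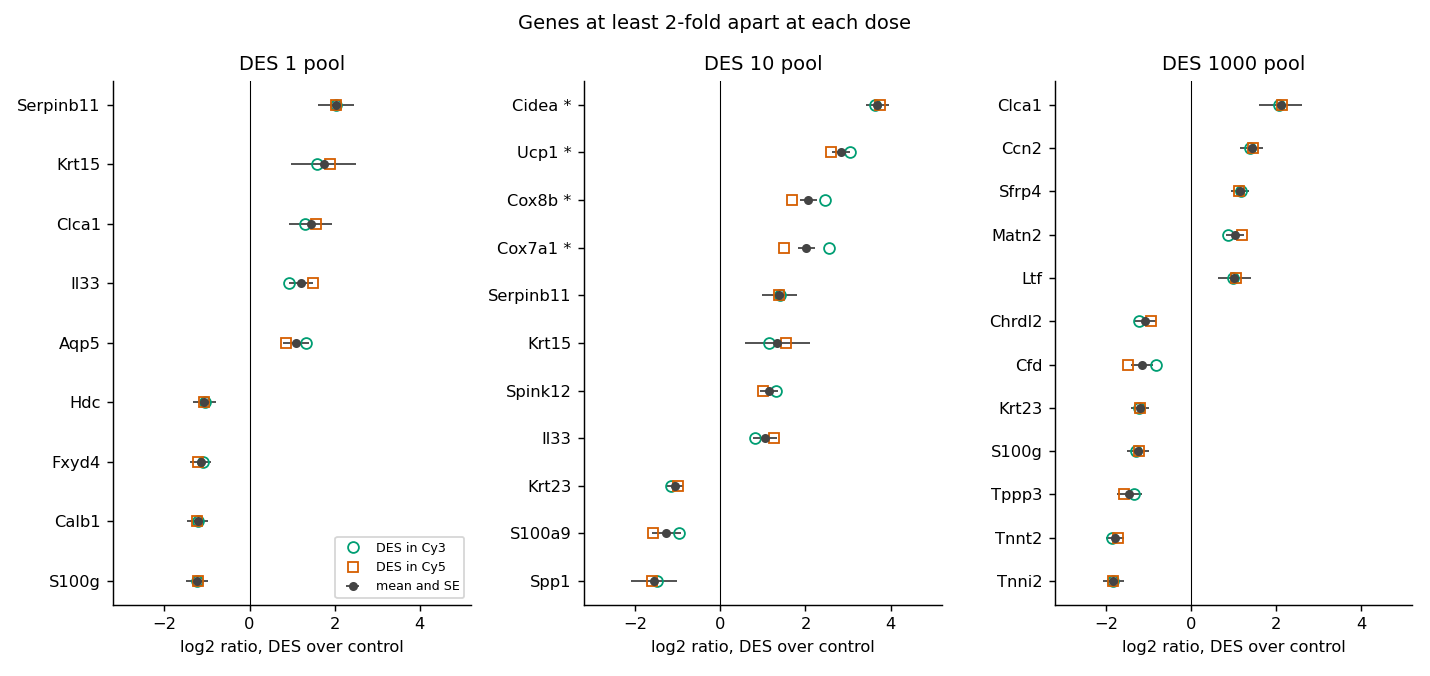
Log2 ratio of the DES pool over its control pool (x axis) for the named genes that met the 2-fold rule at each dose (y axis), with the array that carried DES in Cy3 as a circle, that with DES in Cy5 as a square, and their mean as a dot with the SE from the control pools. The 4 genes with a star, which lie between 2.02 and 3.69 at DES 10, passed the test.

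**Figure D2:**
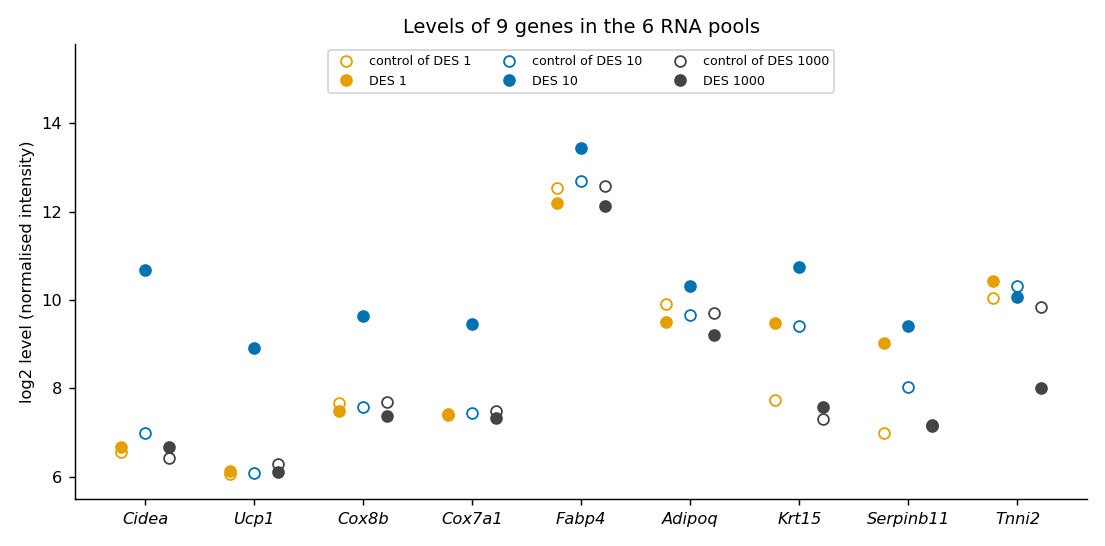
Normalised log2 level (y axis) of 9 genes (x axis) in the 3 DES pools (filled) and the 3 control pools (open). Cidea, Ucp1, Cox8b and Cox7a1 stand apart in the DES 10 pool, Krt15 lies at 9.41 in the DES 10 control pool against 7.74 and 7.31 in the others, and Tnni2 lies at 8.01 in the DES 1000 pool.

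Which genes moved the same way at every dose was asked by testing the mean of the 3 ratios. Genes were named by smallest p, so larger means occur among the rest. Those below 0 included Krt23 at -1.08 ± 0.06 (limma's moderated SE, n = 3 pairs of pools) and S100g at -1.05 ± 0.13. The moderated SE draws on the spread of all probes, not on the 3 ratios of a gene alone. Also below 0 were Cited4, a transcriptional coactivator, at -0.72 ± 0.05, Tnnt1 at -0.67 ± 0.08, Emb at -0.65 ± 0.05 and Coch at -0.61 ± 0.04. Those above 0 included Akr1c14, an enzyme that reduces steroids, at 0.54 ± 0.04, Cfb, the complement factor B, at 0.48 ± 0.05, Msx2, a homeobox gene of the uterine epithelium, at 0.46 ± 0.05, Tmem54 at 0.42 ± 0.04 and the chromatin protein Hmga1 at 0.42 ± 0.03. The stem cell receptor Lgr5 stood at -0.33 ± 0.04, Hoxb6 at -0.29 ± 0.04 and Igfbp6 at -0.38 ± 0.05. All of these were picked for 1 direction on all 6 arrays, which 484 probes had, against 614.2 by chance with independent arrays. The test over the 3 pairs (limma) called 0 probes, with a smallest adjusted p of 0.116, that of Krt23, Cited4 and Coch among others, and 1144 probes at an unadjusted p under 0.05. A fit of all 6 arrays with a dye term and the dose as a random block called 30 probes, 10 higher and 20 lower, of which 22 carry a symbol. In it Krt23 had an adjusted p of 0.00134, Cited4 and Coch 0.0025, Hmga1 0.00607, S100g 0.0277 and Msx2, Cfb and Lgr5 0.0366. Its estimated correlation within a dose was -0.0934, so it counts the 2 arrays of a pair as nearly independent. Treating the DES and control pools as 3 against 3 with no replicate block gave 0 calls.

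Of the genes set for naming before the data were examined, Esr1, the estrogen receptor, stood at 0.04, -0.05 and -0.10 at the 3 rising doses, Pgr, the progesterone receptor, at -0.09, -0.19 and -0.03, and Wnt7a at 0.07, -0.01 and -0.08. Hoxa10 stood at -0.12, -0.14 and 0.14, Hoxa11 at -0.06, 0.05 and -0.03, Wnt5a at -0.01, -0.06 and 0.17, and Egf at 0.00, 0.03 and 0.05. C3, the central complement protein, stood at 0.05, 0.20 and 0.50, Foxa2 at -0.11, -0.34 and -0.66, and Trp63, a regulator of stratified epithelium, at 0.27, 0.56 and 0.12. None of these passed the test at a dose. Fos was not measured.

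**Figure D3:**
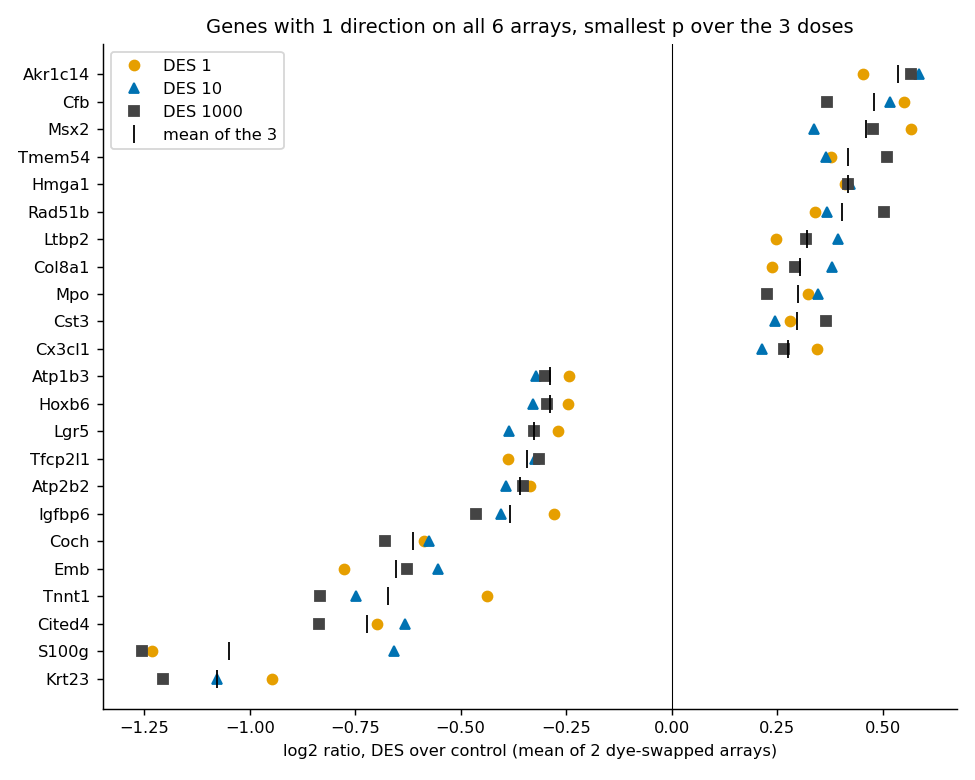
Log2 ratio of DES over control (x axis) at DES 1 (circles), DES 10 (triangles) and DES 1000 (squares) for 23 genes (y axis) with 1 direction on all 6 arrays and the smallest p values over the 3 doses, and the mean of the 3 as a bar. The means run from -1.08 for Krt23 to 0.54 for Akr1c14, and none passed the adjusted threshold in the test over the 3 pairs.

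Gene lists fixed before the data were examined were compared with all other genes over the 3 doses by camera (limma, preset correlation 0.01). Of the 28 lists, 10 passed at an adjusted p under 0.05, 5 higher and 5 lower. With processed signals 5 passed, 4 higher and 1 lower, and without the DES 1000 pair 6 passed, 3 in each direction. All 10 calls end with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, called 0 lists, its smallest adjusted p being 0.291. Fry's mixed test, which asks for change in either direction, passed for patterning genes and complement genes (adjusted p = 0.0286 for both), for estrogen-responsive genes (0.0363) and for uterine gland genes (0.0441). Ltf belongs to the complement, estrogen-responsive and gland lists, and Cfb to the complement and estrogen-responsive lists. The results of these lists are therefore not independent of each other. Over all probes, the only list members past the test at a dose were Cidea and Ucp1 of the adipocyte list at DES 10. The counts below were adjusted over the list alone. At single doses, 31 medians of the 28 lists lay in the outer 5% of random lists (both tails together), 12 higher and 19 lower. Random lists leave out the correlation between the genes of a list, so an extreme percentile is weak evidence.

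Smooth muscle genes had the lowest median, -0.21 over the 3 doses in 19 measured genes (adjusted p = 1.88e-11, and adjusted p = 0.466 with an estimated correlation). Their median was -0.06 at DES 1, -0.29 at DES 10 and -0.28 at DES 1000, and 18 of the 19 were below 0 at DES 10 and 17 at DES 1000. Both of the latter medians lay below those of all 10000 random lists of like size and expression. Adjusted over the list alone, 6 genes passed over the 3 doses, all lower, among them the actins Acta2 at -0.24 and Actg2 at -0.29, the calmodulin-binding protein Pcp4 at -0.29 and phospholamban, Pln, at -0.33. Only 1 of the 19 was lower on all 6 arrays. Pcp4 stood at -0.50, -0.59 and -0.72 on the arrays with DES in Cy3, but at 0.02, 0.02 and 0.05 with DES in Cy5. Hspb1 stood at -0.66 and Myh11, the smooth muscle myosin, at -0.28 at DES 1000. Skeletal muscle genes, 15 measured, had a median of -0.04 and a mean of -0.15 (adjusted p = 0.00517, and adjusted p = 0.466 with an estimated correlation). Few members carried the difference in values. Ckm, Mylpf, Atp2a1, Myh4 and Tnnt3 were dim, with levels of at most 6.98 in every pool, where the offset pulls ratios to 0. Their small ratios therefore say little about skeletal muscle. Acta1 and Tnni2 were brighter, with levels of at least 10.92 and 9.84 in the control pools. Acta1 and Tnni2 passed at DES 1000 adjusted over the list alone, at -0.97 and -1.83, and Acta1 and Tnnc2 over the 3 doses.

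**Figure D4:**
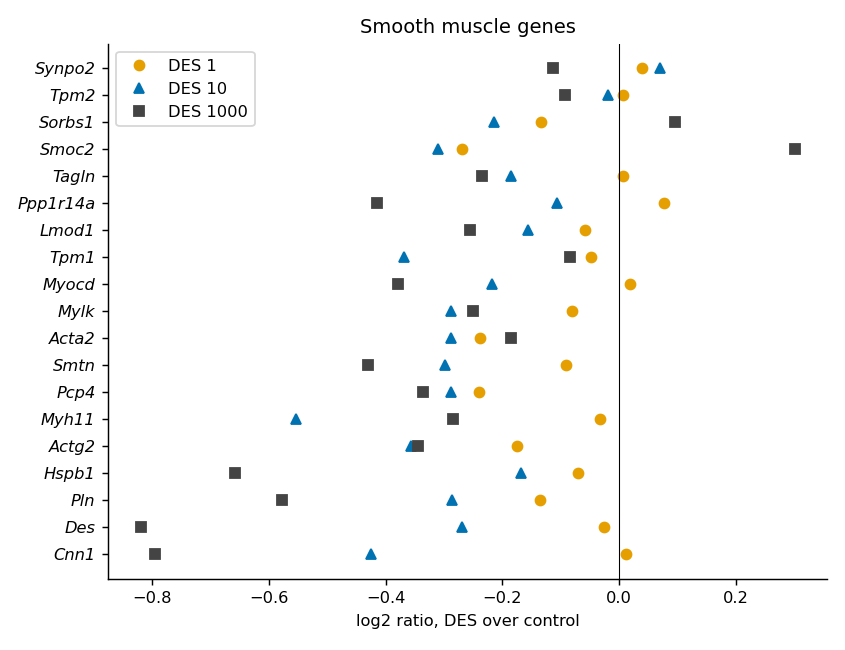
Log2 ratio of DES over control (x axis) of the 19 measured smooth muscle genes (y axis) at DES 1 (circles), DES 10 (triangles) and DES 1000 (squares). Most genes lie below 0 at DES 10 and DES 1000, with Des at -0.82 and Cnn1 at -0.80 at the highest dose, while 6 of 19 lie above 0 at DES 1.

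Cell cycle genes, 29 measured, had a median of 0.09 over the 3 doses (adjusted p = 2.11e-05, and adjusted p = 0.476 with an estimated correlation). At DES 1 their median was 0.22 with 26 of 29 above 0, at DES 10 it was -0.00 with 14 above 0, and at DES 1000 it was 0.05. Mki67 and Tk1, markers of dividing cells, each stood at 0.49 at DES 1, and Ccnb2 at 0.44. No member passed at any dose adjusted over the list alone.

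Markers of squamous and basal epithelium, 14 measured, had a median of 0.10 (adjusted p = 0.000138, and adjusted p = 0.466 with an estimated correlation), with medians of 0.08, 0.18 and 0.05 at the 3 rising doses. Krt15 had the highest mean, and at DES 10 Perp, a desmosomal protein, stood at 0.61, Trp63 at 0.56 and Sprr1a at 0.53. No member passed adjusted over the list alone. Simple epithelium had a median of 0.03 over 23 genes and was not called (adjusted p = 0.237). Cell junction genes, 30 measured, had a median of 0.03 (adjusted p = 0.0426, and adjusted p = 0.466 with an estimated correlation), and the cadherins Cdh2 at 0.25 and Cdh13 at 0.21 passed over the 3 doses adjusted over the list alone. Uterine gland genes, 17 measured, had a median of -0.04 (adjusted p = 0.0274, and adjusted p = 0.466 with an estimated correlation). Calb1 passed at DES 1 adjusted over the list alone, and over the 3 doses Calb1 at -0.78 and Ltf at 0.80 passed in opposite directions. Oviduct and ciliated cell genes had a median of -0.01 over 9 genes and a mean of -0.06, and camera placed them above other genes without calling them (adjusted p = 0.905). Tppp3 passed at DES 1000 adjusted over the list alone.

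The lists of immune cell markers had medians of either sign. Macrophage and myeloid genes, 20 measured, had a median of 0.06 over the 3 doses and of 0.13 at DES 1000 (adjusted p = 0.00178, and adjusted p = 0.466 with an estimated correlation). Ctss, a lysosomal protease of antigen-presenting cells, passed at DES 1000 adjusted over the list alone, at 0.90, and C1qa stood at 0.53. MHC class II genes, 9 measured, had a median of 0.06 (adjusted p = 0.00695, and adjusted p = 0.466 with an estimated correlation), with 0 members past the test adjusted over the list alone. Interferon-induced genes, 22 measured, had a median of -0.04 (adjusted p = 0.00856, and adjusted p = 0.466 with an estimated correlation), and Cxcl10 at -0.27, well above background on 1 of 2 arrays in the DES 1 pool, passed over the 3 doses adjusted over the list alone. Lymphocyte genes had a median of -0.04 over 21 genes (adjusted p = 0.0705) and granulocyte and mast cell genes of -0.00 over 19 (adjusted p = 0.811), and neither was called. Mpo, of neutrophil granules, passed over the 3 doses adjusted over the list alone, at 0.30. Complement and epithelial defence genes, 21 measured, were not called (median 0.01, adjusted p = 0.489). Adjusted over the list alone, Cfd passed at -1.16 at DES 1000, and Cfb and Ltf passed over the 3 doses.

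Among signalling lists, growth factors and receptors, 33 measured, had a median of -0.03 (adjusted p = 0.0426, and adjusted p = 0.466 with an estimated correlation). Igfbp6 at -0.38 and Fst, the activin antagonist follistatin, at -0.31 passed over the 3 doses adjusted over the list alone. WNT and hedgehog genes, 27 measured, were not called over the 3 doses (median 0.01, adjusted p = 0.39). At DES 1000, 4 of them passed adjusted over the list alone, all higher and all secreted WNT antagonists or relatives of these, Sfrp4 at 1.15, Sfrp1 at 0.87, Dkk3 at 0.85 and Sfrp2 at 0.69. Patterning genes of the Müllerian duct, 24 measured, were not called (median -0.02, adjusted p = 0.13), and Msx2 at 0.46 and Gata6 at -0.26 passed over the 3 doses adjusted over the list alone. Their median at DES 1, -0.06, lay at percentile 0.05 of random lists. Estrogen-responsive genes, 33 measured, had a median of -0.01 and a mean of 0.07 and were not called, camera placing them higher (adjusted p = 0.659). Clca1 at 1.44, Ltf at 0.80 and Cfb at 0.48 passed over the 3 doses adjusted over the list alone. Steroid receptors and coregulators had a median of -0.03 over 18 genes (adjusted p = 0.24) with 0 members past the test. Immediate early genes had a median and a mean of 0.00 over 23 genes, and camera placed them lower without calling them (adjusted p = 0.69). Adjusted over the list alone, Ccn2 passed at DES 1000 and Ier3 at -0.31 over the 3 doses. At the rising doses Ier3 stood at 0.00, -0.01 and 0.01 on the arrays with DES in Cy3, but at -0.69, -0.62 and -0.53 with DES in Cy5.

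The remaining lists were not called over the 3 doses. Steroid and xenobiotic metabolism had a median of -0.01 (26 genes, adjusted p = 0.0989), and Cyp1b1 at -0.31, well above background on 1 of 2 arrays in the DES 1 pool, and Aox1 at -0.19 passed over the 3 doses adjusted over the list alone. Retinoid genes had a median of 0.02 (18 genes, adjusted p = 0.425), and Aldh1a1, which makes retinoic acid, passed at -0.44 adjusted over the list alone. Fibroblast and matrix genes had a median of -0.00 and a mean of 0.04, with camera placing them higher (28 genes, adjusted p = 0.519). Their medians were -0.05 at DES 10 and 0.10 at DES 1000, where Lox passed at 0.93 adjusted over the list alone. Endothelial genes had a median of 0.05 (18 genes, adjusted p = 0.0608). Adipocyte genes had a median of -0.02 and a mean of 0.06, with camera placing them lower (17 genes, adjusted p = 0.588). At single doses they were far apart, with medians of -0.05 at DES 1, 0.26 at DES 10 and -0.18 at DES 1000. Adjusted over the list alone, Cidea, Ucp1 and Fabp4 passed at DES 10, all higher, and Cfd and Thrsp at DES 1000, both lower. Erythroid genes had a median of 0.02 and a mean of -0.05, with camera placing them lower (7 genes, adjusted p = 0.519), and Alas2 passed at -0.24 adjusted over the list alone. Ovarian genes had a median of -0.01 (16 genes, adjusted p = 0.856), and their mean of -0.01 turned to 0.05 with processed signals and 0.03 with median centring. Nerve and Schwann cell genes had a median of 0.00 (18 genes, adjusted p = 0.961).

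**Figure D5:**
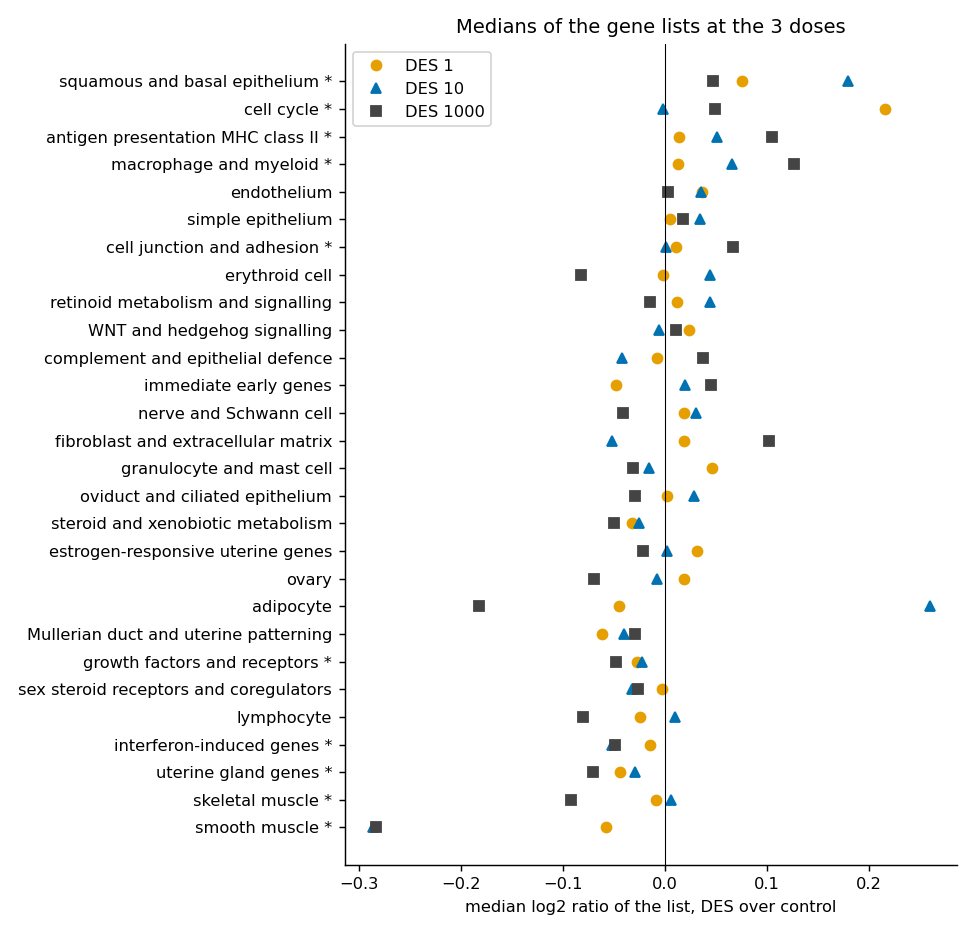
Median log2 ratio of DES over control (x axis) of each of the 28 gene lists (y axis) at DES 1 (circles), DES 10 (triangles) and DES 1000 (squares). A star marks the 10 lists called over the 3 doses by camera with the preset correlation, none of which is called with an estimated one. The adipocyte list has medians of 0.26 at DES 10 and -0.18 at DES 1000.

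Whether the change followed the dose was asked with a slope per 10-fold dose. The smallest p values were those of Tnni2 at -0.75, Serpinb11 at -0.68 and Ccn2 at 0.59 on the log2 scale, each with an adjusted p of 0.11. The trend test (limma) called 0 probes, with 2353 at an unadjusted p under 0.05, on 1 residual degree of freedom. Direct tests of the difference between doses against the spread between control pools (limma's moderated variance) called 0 probes for each pair of doses. At an unadjusted p under 0.05 there were 77 for DES 1000 minus DES 1, 80 for DES 1000 minus DES 10 and 43 for DES 10 minus DES 1. The brown fat genes came nearest, Ucp1 differing by -3.00 between DES 1000 and DES 10 (adjusted p = 0.0542) and Cidea by 3.59 between DES 10 and DES 1 (adjusted p = 0.0611). Median centring gave 1091 calls for the trend and 4 each for the differences that involve DES 10. On the arrays alone (limma, chosen after the values had been seen), 14, 37 and 18 probes differed between DES 1000 and DES 1, DES 1000 and DES 10, and DES 10 and DES 1.

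The doses shared some of the genes that passed the technical test, which uses 1 SE per probe for all doses, so that calls at different doses are not independent. DES 1 and DES 10 had 6 in common that were higher and 4 that were lower. DES 1 and DES 1000 shared 6 higher and 8 lower, and DES 10 and DES 1000 shared 3 higher and 11 lower. Across all probes, where genes are not independent replicates, the ratios of the doses correlated weakly, with r of 0.0894 for DES 1000 and DES 1, 0.168 for DES 1000 and DES 10, and 0.201 for DES 10 and DES 1.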

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

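All tests in this part were chosen after the result was seen, except that of the further brown fat genes and the 2 that turn the sign of a pair, and those for Tnni2, for the other squamous markers and for the spans of Krt15 and Serpinb11 were redefined after a first version's values had been seen. The differences between doses below come from the fit of the 6 arrays (limma), which compares RNA pools and not conditions, and the test against the spread between control pools called 0 of them, with 77, 80 and 43 probes at an unadjusted p under 0.05 for the 3 differences in the order below. Between doses, 14 probes differed for DES 1000 minus DES 1, 37 for DES 1000 minus DES 10 and 18 for DES 10 minus DES 1. The neutrophil protein S100a9 moved in opposite directions, its ratio differing by -2.25 for DES 10 minus DES 1 (adjusted p = 0.00295) and by -1.68 for DES 1000 minus DES 1 (adjusted p = 0.0148). Its level at the rising doses was 8.13, 8.97 and 8.57 in the control pools and 9.11, 7.70 and 7.87 in the DES pools. Part of each difference thus lies in the control pools. Cfd, a protease secreted by fat cells, differed by 1.38 for DES 10 minus DES 1 (adjusted p = 0.00983) and by -1.86 for DES 1000 minus DES 10 (adjusted p = 0.0018). Levels of Cfd at the rising doses were 12.81, 12.25 and 12.62 in the control pools and 12.14, 12.96 and 11.47 in the DES pools. Here too, part of each difference lies in the control pools. The fatty acid carrier Fabp4 differed by -1.20 for DES 1000 minus DES 10 (adjusted p = 0.0078), and Lce1b, of the cornified envelope, by 1.33 for DES 1000 minus DES 10 (adjusted p = 0.00777).

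The first pattern is the rise of Cidea, Ucp1, Cox8b and Cox7a1 in the DES 10 pool, where fat cell genes such as Cfd and Fabp4 were also high. The smallest of the 8 ratios on the arrays was 1.49, which argues against a fault of 1 array or dye. The DES 10 control pool lay only -0.0437 from the other control pools in the median of the 4 genes, so it was not low for them. The test favours genes whose control pools are alike, so this was partly set by how the genes were picked. For Cfd the DES 10 control pool was the low one, at 12.25 against 12.81 and 12.62, so part of its ratio lies there. Brown adipose tissue carried along with the uteri of this pool remains a candidate explanation: 24 further brown fat genes, listed before their values were seen, had a median of 0.135 at DES 10, at percentile 100 of random lists, against percentiles of 3.35 and 7.87 at the other doses, and the 15 adipocyte genes other than Cidea and Ucp1 also lay at percentile 100. Of the brown fat and adipocyte genes, 23 of the 24 and all 15 were above background in every control pool. Since 92.3% to 95.3% of all probes were so in at least 1 dye, this does not show expression by the uteri. Fabp4 and Adipoq, already at 12.69 and 9.67 in the DES 10 control pool, stood at 0.75 and 0.64. Small log2 ratios over high levels do not weigh against added fat. A response of the uterus to this dose was not tested apart from this and stays open, since the dose has 1 pool.

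The next pattern is low muscle genes at DES 10 and DES 1000. The highest of the 4 array medians of the smooth muscle list was -0.24, which argues against dye bias in the list median. Single members such as Pcp4 did differ between the dyes. A lower share of smooth muscle in the DES pools and lower expression per cell were not tested apart, and both stay open. For Tnni2 at DES 1000, skeletal muscle carried along with the control uteri of that pair would make it high in that control pool, yet it lay there at -0.343 from the mean of the other control pools on the log2 scale, against a ratio of -1.83, which argues against it.

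The last pattern is high Krt15 and Serpinb11 at DES 1 and DES 10. The other 13 squamous markers measured had medians of only 0.07 and 0.12, but these lay at percentiles of 99.99 and 100 of random lists, with 11 of the 13 above 0 at each dose. Squamous tissue carried along with the uteri therefore remains a candidate explanation, and so does a change of the uterine epithelium with DES, which was not tested apart from it. The control pools spanned 2.10 on the log2 scale for Krt15 and 1.04 for Serpinb11, but the ratios are paired on the array, and the paired ratios of the 3 doses spanned 1.47 and 2.03. The smaller span of each gene, 1.47 and 1.04, lies between the mean of its ratios at DES 1 and DES 10 and 50% of it. The span of the ratios holds the pattern itself, so this comparison cannot decide. With 1 pool per dose, pool differences and DES cannot be told apart.

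The 3 pairs of pools give 4 ways of turning the sign of none or 1 pair, too few for a share under 0.05. The real count of probes called over the 3 doses was 0 and the highest of the others was 0, so that 4 of 4 gave as many. For gene lists the real count was 10 and the highest of the others 5, so that 1 of 4 gave as many.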

How the results depend on the processing

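The technical test, its settings, the fit without a block and the lists without muscle and fat genes were chosen after the result was seen. Of the 161 values of genes set for naming, 155 to 161 kept their direction in each setting tried. Only 1 value larger than its SE turned its direction, that of Figla at DES 1000, at -1.17 without DES 1000 replicate 1 and 0.0853 without DES 1000 replicate 2. The causes below were not tested, except where fewer arrays or pools are used. Closeness to the background limits the ratios of dim probes.

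With Feature Extraction's processed signals, DES 10 gave 0 calls, the 2-fold counts were 29, 39 and 82 at the rising doses, the technical counts 1, 7 and 7, the called lists 5 and the control SD 0.22. The series matrix gave 0 calls at DES 10, 2-fold counts of 27, 39 and 79 and technical counts of 1, 7 and 7. An offset of 10 gave 0 calls at DES 10, 2-fold counts of 23 at DES 10 and 45 at DES 1000, and technical counts of 10, 21 and 70. No background subtraction gave 15 2-fold probes at DES 1000 and technical counts of 29 at DES 10 and 106 at DES 1000. Median centring gave 1 call at DES 1, 5 at DES 1000, 4 for DES 1000 minus DES 10, 4 for DES 10 minus DES 1, 1 over the 3 doses, 1091 for the trend, and technical counts of 3, 7 and 16. Scaling between arrays gave 1 call over the 3 doses (Krt23), 15 2-fold probes at DES 1 and technical counts of 15 at DES 10 and 0 at DES 1000.

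With the control pool of DES 1 left out of the spread, the calls were 3 at DES 1, 8 at DES 1000, 3 for DES 1000 minus DES 1, 4 for DES 1000 minus DES 10 and 5 for DES 10 minus DES 1. Without the DES 10 control they were 1 at DES 1, 3 at DES 1000, 4 for DES 1000 minus DES 10 and 3 for DES 10 minus DES 1. Without the DES 1000 control they were 1 at DES 1, 7 at DES 1000, 1 for DES 1000 minus DES 1, 4 for DES 1000 minus DES 10 and 4 for DES 10 minus DES 1. The residual SD as the spread, which takes in the change at a single dose itself, gave 0 calls at DES 10. An intensity trend gave 2 calls for DES 1000 minus DES 10 and 2 for DES 10 minus DES 1. All controls as 1 group gave 2 calls at DES 1000. The software's own p gave 44, 51 and 113 probes at the rising doses, the technical test 25, 52 and 183, and a size of 1.5-fold 41, 57 and 139.

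The 6 arrays with the dose as a random block gave 30 calls over the 3 doses and 157 for the trend, and 23 without a block. Leaving out the DES 10 pair gave 1 call over the 3 doses. The called lists were 0 with an estimated correlation and 6 without the DES 1000 pair, and 8 without muscle and fat genes.

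With 1 array left out, a lone array is assumed to vary like the others. Calls at DES 10 were 0 to 4, with 0 without DES 10 replicate 1 and 2 without DES 10 replicate 2 or DES 1000 replicate 2. The range was 0 to 3 for DES 1000 minus DES 10, 0 to 1 for DES 10 minus DES 1, 0 to 3 for the trend, and 0 for the other tests. The 2-fold counts were 11 to 27 at DES 1, 13 to 25 at DES 10 and 24 to 44 at DES 1000, under a looser rule that asks only for 2-fold on the lone array. Of the other values, 246 list results and 1729 gene values kept their call and direction. Of list results, 8 gained a call, 32 lost one and 19 uncalled ones moved, and of gene values 7 gained a call, 16 lost one and 18 uncalled ones moved.

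A block for the slide or day could not be run, since every slide held 1 array and all were read on the same day.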

Other observations

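Apart from the list of further brown fat genes, the genes in this part were chosen, and the technical test was added, after the result was seen. The zinc transporter Slc39a4 stood at -0.78 at DES 1, the glutathione transferase Gsto1 at -0.69 at DES 1 and -0.65 at DES 1000, and the membrane linker Ezr at -0.64 at DES 1 and -0.58 at DES 10. The chemokine Cxcl14 stood at 0.73 at DES 1 and 0.61 at DES 1000. At DES 10, Ly6d stood at 0.93, Anxa8 at 0.87, Fabp3 at 0.91 and Apoc1 at 0.89. At DES 1000, Apoe stood at 0.80, the iron exporter Slc40a1 at 0.91, the transcription factor Snai2 at 0.92 and the basement membrane collagen Col7a1 at 0.92, while the macrophage chemokine Ccl8 stood at -0.93 and Retnla at -0.72. All of these passed the technical test at the doses given, and none passed the test against the spread between control pools.

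Of 24 further brown fat genes, those with the highest ratios at DES 10 were Fabp3 at 0.91, Pdk4 at 0.65 and Sdhb at 0.39, and 18 of 24 were above 0 there, against 6 at each of the other doses. Of these 3, Fabp3 passed the technical test. Members with low ratios at DES 10 included Dio2 at 0.12, Elovl3 at 0.03, Ucp3 at -0.03 and Ppargc1a at -0.07.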
